A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

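Cultures of an HA-TBP strain and of an untagged strain were grown at 25 °C to an optical density of 0.8, brought to 37 °C for 5 min by adding heated medium, cooled, cross-linked with 1% formaldehyde for 15 min, quenched with 0.25 M glycine for 5 min and harvested at 4 °C, per the labels. The ChIP DNA was in channel 1 on 2 of the 3 HA-TBP arrays and in channel 2 on the other, and the untagged strain had 1 array of each order. Images were scanned on a GenePix 4000A and quantified with GenePix Pro 4.0, per the labels. Background subtraction, normalization, filtering and the direction of the ratio are not given in the sources used here.

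The deposited values are log2 ratios of the channels, per the values themselves. They were not centred: the medians were -1.59, -4.51 and -5.20 on the HA-TBP arrays and -1.76 and -4.40 on the untagged arrays. Arrays of opposite channel order correlated positively, so all columns run the same way, taken as ChIP over input. Many deposited log2 values equal the log2 of a fraction of small whole numbers. A spot was called dim if its ratio equals a fraction with both terms up to 200, within 1e-06. By this, 17.6, 10.8 and 9.30% of spots on the HA-TBP arrays and 11.9 and 9.04% on the untagged arrays were dim, where shifted values matched by accident in at most 0.63%. No intensities were used, so signal over background is unknown.

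The platform annotation gave 5696 of the 7047 probes 1 gene symbol, 0 several and 1351 none, and 5693 matched the yeast assembly R64. The assembly was used only for names and for which genes neighbour each other, because the build behind the array is not given in the sources used here. A region was taken to lie between its named gene and the next gene to the right. This was checked from naming alone: of genes whose right neighbour overlaps them, 8.16% (8 of 98) name a region, against 41.7% (48 of 115) for a left neighbour that overlaps and 86.7% otherwise. The check was first run on neighbours that overlap or lie within 50 bp, which gave 10.2 and 54.6% against 88.0%. Both neighbours were known for 5328 of the regions measured on all arrays and unknown for 894. A tRNA, SNR6, SCR1, RPR1 or 5S ribosomal RNA neighbour made a region one beside a polymerase III gene.

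Each array was centred on its median, and regions measured on all 5 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), with terms for the strain and for the channel of the ChIP DNA; all arrays shared the estimate of spread, with 2 residual and 2.67 prior degrees of freedom. The dye term passed the test in 0 regions with limma, at an unadjusted p under 0.05 in 634. Calls used a Benjamini-Hochberg adjusted p under 0.05. Differences are these dye-adjusted estimates with their SE, so they can differ from the difference of the group means. At YNCD0012W-UBC5 the estimate was 3.54, with group means of 3.18 in HA-TBP and 0.32 in the untagged strain. Lists were tested with camera at a preset correlation of 0.01 and with an estimated one, over 5328 regions, adjusted over 11 lists. With an estimated correlation camera tests on the 2 residual degrees of freedom, so few lists can pass. A region belonged to a list if it is immediately upstream of a member. Each probe counts as a region, and 218 genes name more than 1 probe, so a gap can count several times. A region named below can be 1 probe of several in its gap. This holds for HIS4-BIK1, HXK1-YFR054C and GAL7-GAL10, with 3 probes each. It also holds for YDR170W-A-HSP42, STE3-LST4, ERB1-YNCM0021C, IME1-IRT1 and CYC3-CDC19, with 2 probes each. Tables were joined with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.

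The regions named were the 12 with the largest and the 5 with the lowest difference among those past the test with every HA-TBP array on the same side of both untagged arrays, the 2 highest and the lowest of each list, and always those upstream of SSA1, HSP26, HSP104, HSP12, TDH3, PGK1, ADH1, RPL3, GAL1, SPT15 and ACT1. Of these, SSA1, HSP12, PGK1, RPL3 and ACT1 had no region named upstream of them with a value on all 5 arrays. The rule, the lists and most alternatives were written before the data were examined.

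The fit was tested on simulated data with 200 of 6222 regions changed between the strains. A log2 change of 2 was recovered in 86.5% of changed regions, with 15 false calls among 188, and changes of 0.5 and 1 in 0%. These shares do not carry over to the data, where 2518 regions had an unadjusted limma p under 0.05. There 646 of 918 higher calls and 31 of 468 lower calls were over 2-fold. The other calls were of sizes that the simulation did not recover. In simulated lists of 20 regions, a shift of 0.5 was found in 100% of 100 draws and no shift in 2%. The simulated regions varied independently. The 2% therefore does not carry over to lists whose regions vary together. Estimated correlations were 0.48 for ribosomal proteins and 0.51 for polymerase III genes. The alternatives were other centrings, scalings and filters, no dye term, array weights, other thresholds and leaving out each array; those on dim spots, probe numbers and neighbours were added after seeing the data. The comparison of promoters with and without a TATA box was left out, because it needs a genome sequence, which was not used here.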

Results

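TATA-binding protein (TBP), the general factor that RNA polymerases I, II and III all need to start transcription, was mapped over the intergenic regions of budding yeast, Saccharomyces cerevisiae. Chromatin immunoprecipitation (ChIP) was run on a strain whose TBP carries an HA tag and on an untagged strain, in which whatever is precipitated is background. Each of the 5 arrays compared ChIP DNA with unpurified input DNA of the same strain in separate colours. There were 3 HA-TBP arrays and 2 untagged arrays. In both strains the cells had been shifted from 25 to 37 °C for 5 min before cross-linking, so no unheated sample was compared. The title of the series names genes with a TATA box, but that comparison needs promoter sequence and was not run here.

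Of 7047 regions listed, between 6577 and 6751 had a value on each array, and 6222 had a value on all 5. Values are log2 ratios centred on each array's median. The labels give the channel of the ChIP DNA but not the direction of the deposited ratio. ChIP over input is the likely direction, because the upper tail of the HA-TBP arrays held the regions beside genes of RNA polymerase III, which need TBP, and the untagged arrays did not show this. With the sign turned, every "higher" below would read "lower". A region is named by its left and right neighbouring genes. Nothing in the labels says that arrays came from separate cultures, so limma p-values of single regions measure the spread between arrays, which may be technical. Having 3 against 2 arrays limits the precision. Fisher's exact, sign, McNemar and permutation tests count regions or genes as independent. These share the same 5 arrays, so such p-values measure no spread between arrays and may be too small.

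The arrays of HA-TBP resembled each other more than they resembled the untagged ones. Across 6222 regions, Pearson's r between HA-TBP arrays was 0.83, 0.69 and 0.77. It was 0.28 between the untagged arrays and between 0.05 and 0.43 across strains. These are correlations across regions, which are not independent replicates. The untagged arrays were narrower, with a median absolute deviation of 0.22 and 0.30 on the log2 scale against 0.60 to 0.61 in HA-TBP. Between 15.2 and 18.5% of regions lay over 1 log2 unit above the median on the HA-TBP arrays, against 4.13 and 7.57% on the untagged arrays.

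ChIP over input was higher in HA-TBP than in the untagged strain at 918 regions, 14.8% of those tested, and lower at 468, or 7.52%. The regions with the largest differences lay mostly beside transfer RNA (tRNA) genes, which RNA polymerase III transcribes. Among the 100 called regions with the largest differences, 65 adjoined a polymerase III gene and 28 had neighbours that are not known here. The region between the tRNA genes YNCG0028W and YNCG0029C was 3.55 ± 0.16 (log2 difference ± SE) higher in HA-TBP, or 11.7-fold. Its centred value was 3.58 ± 0.26 (SD, n = 3) in HA-TBP and -0.02 ± 0.06 (SD, n = 2) in the untagged strain. The regions MIM1-YNCO0008W (3.54 ± 0.26), YNCP0007C-YPL060C-A (3.42 ± 0.27), YNCJ0019C-NOP9 (3.36 ± 0.16), YNCD0005C-YDL007C-A (3.36 ± 0.39) and YIL102C-YNCI0002W (3.35 ± 0.16) each adjoin a tRNA gene as well. YNCD0005C-YDL007C-A had a dim spot, one whose ratio came from small whole numbers, on 3 arrays, and its untagged values were -1.94 and 0.44.

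Protein-coding neighbours were rarer at the top. The region between SOP4 and RPS14B, which encodes a protein of the small ribosomal subunit, was higher by 3.50 ± 0.27, or 11.3-fold, with 3.43 ± 0.65 (SD, n = 3) against -0.18 ± 0.04 (SD, n = 2). ENA1-RSM10 (3.50 ± 0.79) and the convergent region ZNF1-YFL051C (4.33 ± 0.83) were also among the 12 largest, but their ratios came from dim spots on 4 and 5 arrays. ZNF1-YFL051C lost its call without HA-TBP array 3 or untagged array 2 (3.17 each) and without untagged array 1 (5.88), and ENA1-RSM10 without these (2.39, 2.39 and 5.00) and without HA-TBP array 1 (3.28). Dim spots on 5 arrays also gave the ratios of an unnamed region, probe 2640 (4.37 ± 0.70). Unnamed probes 3216 (3.83 ± 0.18) and 783 (3.48 ± 0.18) had no dim spot. The lowest differences were those of YDR262W-DIN7 (-1.85 ± 0.44), RET3-RQC2 (-1.66 ± 0.13), ALD2-EAR1 (-1.63 ± 0.25), RPS16A-FDO1 (-1.46 ± 0.13) and unnamed probe 6569 (-1.42 ± 0.25). In these 5 regions the untagged mean lay between 0.83 and 1.22 above the median, while the HA-TBP mean lay between -0.75 and -0.28. YDR262W-DIN7, RET3-RQC2, ALD2-EAR1 and RPS16A-FDO1 had a dim spot on 1 or 2 arrays. YDR262W-DIN7, RET3-RQC2, RPS16A-FDO1, YNCD0005C-YDL007C-A and probe 3216 lie among probes 3001 to 3300, where untagged array 1 was over 1 above its median in 12.8% of regions, against 1.67% elsewhere, and untagged array 2 in 6.38% against 3.46%. YDR262W-DIN7 stood at 2.34 on untagged array 1 and at 0.09 on untagged array 2, and without untagged array 1 it gave -0.80 and did not pass (limma adjusted p = 0.14). Without that array ALD2-EAR1 (-1.08), RPS16A-FDO1 (-1.34) and probe 6569 (-1.76) did not pass either, while RET3-RQC2 did (-1.66). Also short of the test were YDR262W-DIN7 without HA-TBP array 1 (-1.70) or 2 (-1.74), ALD2-EAR1 without HA-TBP array 1 (-1.56), and probe 6569 without HA-TBP array 3 or untagged array 2 (-1.16 each).

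These calls are from limma with a dye term per region and a Benjamini-Hochberg adjusted p under 0.05. In 57.9% of regions every HA-TBP array lay on the same side of both untagged arrays, where chance gives 20% if arrays are interchangeable. This held for 908 of the 918 higher regions. Those were called on the same arrays, which favours such regions, so the 908 adds no separate support. The balance depended on the centring: of all calls, 66.2% were higher, and 89.9% were higher with arrays centred on their mode, which raised the median difference of all regions from -0.04 to 0.11. Quantile normalization and the values as deposited left 0 calls in either direction with limma, at an unadjusted p under 0.05 in 2249 and 15 regions. Without HA-TBP array 1, 2 or 3, 49, 74 and 73 regions were lower. Both directions lost most calls without untagged array 1. In that fit the dye term leaves the difference as HA-TBP array 3 minus untagged array 2, 1 array against 1. Calls lost in that fit do not by themselves show that untagged array 1 drove them.

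Before the untagged strain was subtracted, 1610 regions of HA-TBP passed the limma test as above their array medians and 1558 as below, with 871 above without HA-TBP array 3. In the untagged strain 0 regions passed the limma test in either direction, and 879 had an unadjusted p under 0.05. With arrays scaled to the same median absolute deviation, 520 untagged regions passed as above 0, and 38 did so without HA-TBP array 2 and 3 without untagged array 1.

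Regions between convergent genes had lower ratios than those between divergent or tandem genes. The mean log2 difference was 0.16 over 1259 regions between divergent genes, which hold a promoter on each side. It was -0.01 over 2334 regions between genes in tandem. Over 1211 regions between convergent genes, which hold only the ends of those genes, it was -0.30. Of the convergent regions, 17 were higher and 216 lower. Of the divergent regions, 173 were higher and 41 lower. The 430 regions beside polymerase III genes averaged 1.80, and 351 of them, 81.6%, were higher while 2 were lower; without untagged array 1, 188 were higher, and without each other array 328 to 333. The 42 regions beside genes of small nucleolar RNAs, which guide modification of ribosomal RNA, averaged 0.79, with 20 higher and 0 lower; without untagged array 1, 5 were higher, and without each other array 12 or 13. Convergent regions were called lower more often than other regions with known neighbours (Fisher's exact test, odds ratio 4.21, adjusted p = 4.5e-41). Regions beside polymerase III genes were called higher more often (Fisher's exact test, odds ratio 51.0, adjusted p = 2.1e-253). The direction of the ratio was itself taken from regions beside polymerase III genes, so the sign of their difference is not a separate result. Divergent regions were neither detectably commoner nor rarer among the higher calls (odds ratio 0.98, adjusted p = 0.85), and the alternatives went both ways. They were commoner with arrays centred on their mode (1.21, Fisher's exact p = 0.024), without dim spots (1.25, p = 0.012) and at an adjusted p under 0.10 (1.32, p = 7.4e-04), and rarer with the looser filter (0.79, p = 0.031), at an adjusted p under 0.01 (0.35, p = 2.2e-11) and with any 1 array left out (0.17 to 0.62, Fisher's exact p at most 3.3e-05). With arrays centred on their mode, 53 convergent and 9 divergent regions were lower and 22 and 236 higher (odds ratio of convergent regions among lower calls 3.38, Fisher's exact p = 1.6e-09). Without untagged array 1, 5 convergent regions and 1 divergent region were lower and 6 and 12 higher, and the odds ratio for convergent regions did not pass (2.13, Fisher's exact p = 0.19). Without HA-TBP array 3 or untagged array 2 it did not pass either (1.57, Fisher's exact p = 0.085).

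**Figure D1:**
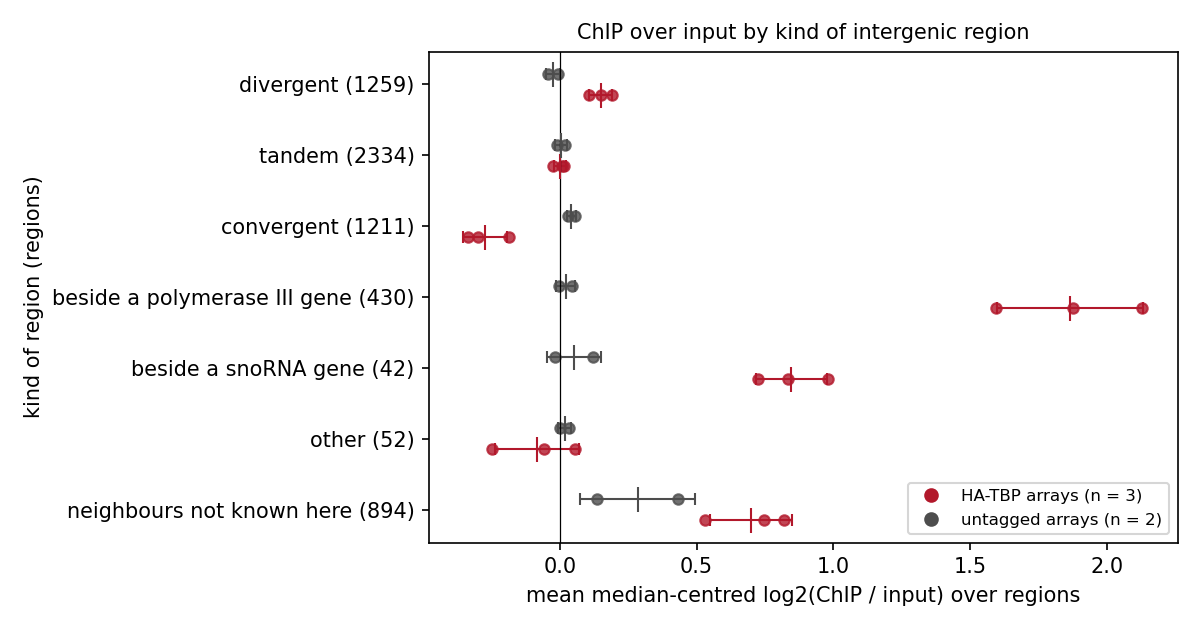
Mean median-centred log2 ratio of ChIP over input (horizontal axis) for each kind of intergenic region (vertical axis, number of regions in parentheses); points are arrays of HA-TBP (n = 3) or the untagged strain (n = 2), ticks are their means and bars their SD. Regions beside polymerase III genes lay at 1.87 on average in HA-TBP and 0.02 in the untagged strain, and convergent regions at -0.27 and 0.04.

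The divergent regions exceeded the convergent ones by 0.47 on the log2 scale, or 1.38-fold (camera p = 3.4e-24, and p = 0.023 with an estimated correlation). Tandem regions exceeded convergent ones by 0.29 (camera p = 1.4e-10, and p = 0.011 with an estimated correlation). Divergent regions exceeded tandem ones by 0.17 (camera p = 3.8e-04), a call that was lost with an estimated correlation (p = 0.16). On single arrays the gap between divergent and convergent regions was 0.42 ± 0.12 (SD, n = 3) in HA-TBP and -0.07 ± 0.04 (SD, n = 2) in the untagged strain.

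The gene lists were written before the data were examined. With an estimated correlation camera has only 2 residual degrees of freedom, so few lists could pass. Glycolysis and histones lost their calls although their estimated correlations, -0.05 and 0.002, were below the preset 0.01. A call lost in that setting therefore does not by itself argue against a shift. The preset in turn makes little allowance for regions that vary together. Regions upstream of ribosomal protein genes lay 0.88 above other regions, or 1.84-fold, and 82 of 118 were higher, with 1 lower. With camera at its preset correlation the adjusted p was 2.5e-23, and the call was lost with an estimated correlation (adjusted p = 0.48). Adjusted over the list alone, 97 were higher and 2 lower. SOP4-RPS14B led the list, followed by TRR4-RPL26A (2.16 ± 0.20), which also adjoins a tRNA gene and lost its call without untagged array 1 (1.90). The lower member was TEM1-RPS1B (-0.59 ± 0.13), whose call was lost with any 1 array left out (limma adjusted p between 0.088 and 0.25). Upstream of genes of glycolysis and fermentation, 9 of 13 regions were higher and 0 lower, and the list lay 0.82 above the rest (adjusted p = 4.0e-05, and adjusted p = 0.44 with an estimated correlation), or 1.35 above over tandem regions only. Its leaders were TDH3, the main glyceraldehyde-3-phosphate dehydrogenase (2.15 ± 0.16, 4.44-fold), and FBA1, aldolase (1.97 ± 0.13, 3.91-fold). The region upstream of ADH1, the main alcohol dehydrogenase of fermentation, was higher by 1.21 ± 0.20, a call lost without untagged array 1 (1.05) and without HA-TBP array 3 or untagged array 2 (1.33 each). The lowest member, 1 of 2 probes named for CYC3-CDC19, gave -0.07 ± 0.15 and did not pass, with -0.22 to 0.13 when 1 array was left out. Adjusted over the list alone, 9 were higher. Regions upstream of histone genes lay 1.06 above the rest, and 3 of 4 were higher, also when adjusted over the list alone. The limma camera test gave an adjusted p = 0.021, and an adjusted p = 0.44 with an estimated correlation; in HA-TBP alone the list lay at 0.90 and did not pass (adjusted p = 0.065). HTA2-HTB2 gave 1.73 ± 0.23 and HTB1-HTA1 1.52 ± 0.13, and both calls were lost without untagged array 1 (1.46 and 1.49), while HTZ1-PLB3, upstream of the gene of the variant histone H2A.Z, gave -0.06 ± 0.14 and did not pass, with -0.14 to 0.05 when 1 array was left out.

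Ribosome biogenesis genes lay 0.39 above the rest, with 5 of 19 regions higher and 0 lower, and 5 higher adjusted over the list alone. The adjusted p was 0.021, and the call was lost with an estimated correlation (adjusted p = 0.71), with scaled arrays (0.20, adjusted p = 0.27), over tandem regions only (0.27, adjusted p = 0.26), without HA-TBP array 1 (0.31, adjusted p = 0.088) and without untagged array 1 (0.32, adjusted p = 0.14). Its leading members, ERB1-YNCM0021C (2.36 ± 0.31) and RPA135-YNCP0010W (1.71 ± 0.18), lie between a listed gene and a tRNA gene, as 3 of the 19 regions did. Without regions beside polymerase III genes the list lay at 0.25 (camera adjusted p = 0.048, and 0.70 with an estimated correlation). RPA135-YNCP0010W lost its call without untagged array 1 (1.78). The lowest member, DBP3-HNM1 (-0.40 ± 0.32), did not pass, with -0.66 to -0.19 when 1 array was left out. The 430 regions beside polymerase III genes lay 1.84 above the rest, or 3.57-fold, with 369 higher and 6 lower adjusted over the list alone. The adjusted p was 1.1e-64, and the call was lost with an estimated correlation (adjusted p = 0.44). YNCG0028W-YNCG0029C led that list. The next, YNCD0012W-UBC5 (3.54 ± 1.05), and the lowest, ESC2-YNCD0026W (-1.75 ± 1.12), did not pass. YNCD0012W-UBC5 had a dim spot on all 5 arrays, with 0.00, 3.19 and 6.37 on those of HA-TBP, and passed at 4.46 without HA-TBP array 1 (adjusted p = 0.0093). ESC2-YNCD0026W lies among probes 3001 to 3300 and gave 1.02 without untagged array 1, while without HA-TBP array 3 or untagged array 2 it passed at -3.83.

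In the untagged strain the ribosomal protein regions lay 0.11 below the rest (shift -0.11, camera adjusted p = 0.0015) and the general stress regions at -0.20 (camera adjusted p = 0.019). Both used the preset correlation, and an estimated one was not tried for this strain.

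**Figure D2:**
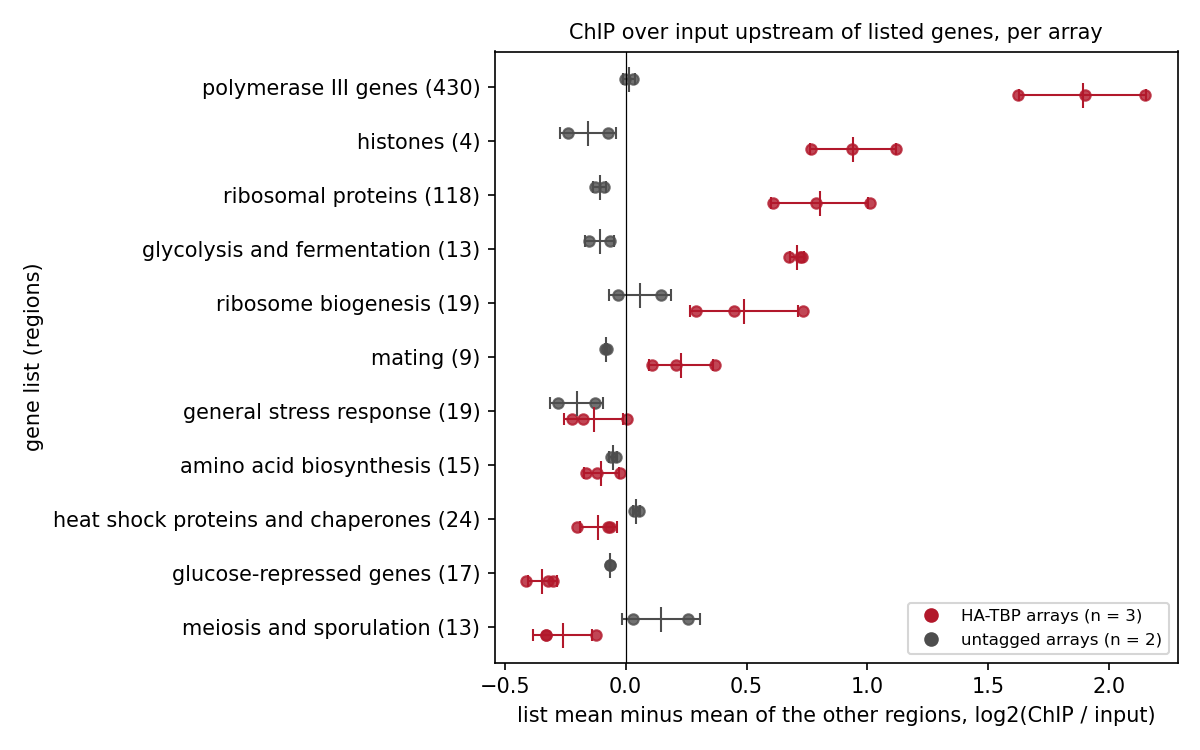
Mean log2 ratio of ChIP over input upstream of each list's genes minus the mean of the other regions (horizontal axis) for 11 gene lists (vertical axis, number of regions in parentheses); points are arrays of HA-TBP (n = 3) or the untagged strain (n = 2), ticks are their means and bars their SD. Ribosomal protein regions lay at 0.80 ± 0.20 in HA-TBP and -0.11 ± 0.03 in the untagged strain. The call for this list was lost with an estimated correlation (camera adjusted p = 0.48), where few lists could pass.

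Regions upstream of heat shock protein genes did not stand out as a list after 5 min at 37 °C. Of 24 regions upstream of heat shock proteins and chaperones, 2 were higher and 2 lower, and the list lay at -0.15 relative to the rest (camera adjusted p = 0.74). It lay at 0.05 over regions whose neighbours have consecutive systematic numbers and at -0.10 without untagged array 1, and did not pass in either. The higher regions were those of YDJ1, an Hsp40 co-chaperone (0.83 ± 0.13), and of UBI4, the polyubiquitin gene (0.75 ± 0.17). Both calls were lost with any 1 array left out (limma adjusted p between 0.053 and 0.16 for YDJ1-MTQ1 and between 0.083 and 0.16 for UBI4-ENT4). The lowest was 1 of 2 probes named for YDR170W-A-HSP42, upstream of a small heat shock protein gene, at -1.32 ± 0.23. Its centred value was 0.56 ± 0.75 (SD, n = 3) in HA-TBP and 2.04 ± 0.40 (SD, n = 2) in the untagged strain. Without untagged array 1 the difference was -0.93 and did not pass (limma adjusted p = 0.17). The regions upstream of HSP26 (-0.22 ± 0.13) and HSP104, the disaggregase (-0.08 ± 0.17), did not pass, and ISA1-HSP104 ranged from -0.19 to 0.01 with 1 array left out. HSP26, HSP104 and HSP42 each lie to the right of the gene naming their region. Probes may not always reach the right-hand gene, so these promoters could lie outside the probes. SSA1 and HSP12 had no region named upstream of them with a value on all 5 arrays. Adjusted over the list alone, 1 region was higher and 1 lower.

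General stress genes lay at 0.05 relative to the rest (adjusted p = 0.74), with 3 of 19 regions higher and 1 lower, the same counts as adjusted over the list alone. The highest was YNCP0023W-GPH1 (1.68 ± 0.20), upstream of glycogen phosphorylase and beside a tRNA gene, which lost its call without untagged array 1 (adjusted p = 0.087). TPS1-MEO1 (1.00 ± 0.50) had a dim spot on 4 arrays and did not pass; with 1 array left out it ranged from 0.57 to 1.58, and it passed at 1.43 without HA-TBP array 1 (adjusted p = 0.020). HXK1-YFR054C was lower (-0.63 ± 0.12), a call lost with any 1 array left out (limma adjusted p between 0.074 and 0.19). The list's mean was 0.16 and its median -0.00. Relative to the rest it lay at 0.23 with scaled arrays, at -0.16 in HA-TBP alone and at -0.08 over tandem regions only, and passed under none of these 3 (adjusted p = 0.21, 0.45 and 0.80).

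Genes repressed by glucose lay at -0.27 (adjusted p = 0.16), with 1 of 17 regions higher and 2 lower, and 1 higher and 5 lower adjusted over the list alone. The list lay at -0.14 with scaled arrays, and passed over regions whose neighbours have consecutive systematic numbers (-0.28, adjusted p = 0.041) and without regions beside polymerase III genes (-0.40, adjusted p = 0.048), but with an estimated correlation it passed in neither (adjusted p = 0.51 and 0.45) nor over all regions (adjusted p = 0.48). The higher region, FBP1-YNCL0047W (1.64 ± 0.16), adjoins a tRNA gene and lost its call without untagged array 1 (1.40). ACS1-FLC2 gave 0.46 ± 0.17 and did not pass (0.26 to 0.74 with 1 array left out), and GAL7-GAL10 was lower (-0.83 ± 0.14), a call lost with any 1 array left out (limma adjusted p between 0.061 and 0.19). The 3 probes between GAL10 and GAL1, galactose-induced genes, gave -0.53 ± 0.13, -0.28 ± 0.14 and -0.42 ± 0.19, and none of these 3 passed; with 1 array left out they ranged from -0.61 to -0.48, from -0.37 to -0.21 and from -0.64 to -0.12. Genes of meiosis and sporulation lay at -0.40 (adjusted p = 0.088; 0.033 without HA-TBP array 1 and 0.011 without untagged array 1), with 0 of 13 regions higher and 2 lower, and 1 higher and 5 lower adjusted over the list alone. IME1-IRT1 (0.79 ± 0.20), REC8-YNCP0009W (0.18 ± 0.24) and PDA1-DMC1 (-1.15 ± 0.32) did not pass. PDA1-DMC1 passed at -1.90 without untagged array 1 (adjusted p = 0.035) and gave -0.59 without HA-TBP array 3 or untagged array 2, and REC8-YNCP0009W ranged from -0.14 to 0.43 with 1 array left out. The list passed with scaled arrays (-0.42, adjusted p = 0.040), with consecutive systematic numbers (-0.37, adjusted p = 0.041) and without regions beside polymerase III genes (-0.44, adjusted p = 0.048). With an estimated correlation it passed under none of the settings named here (adjusted p between 0.56 and 0.87, and 0.71 over all regions and arrays).

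Amino acid biosynthesis lay at -0.06 with an adjusted p = 0.86, and 1 of 15 regions was higher and 2 lower, as also when adjusted over the list alone. The mean shift and the camera direction of this list differed in sign, and the shift was 0.02 with scaled arrays and 0.10 with consecutive systematic numbers. ILV5-ATG33 was higher (1.17 ± 0.16), a call lost without untagged array 1 (1.01), SHM2-REX2 gave 0.69 ± 0.18 and did not pass, and HIS4-BIK1 was lower (-0.67 ± 0.12), a call lost with any 1 array left out (limma adjusted p between 0.066 and 0.17). Mating genes lay at 0.29 (adjusted p = 0.34), with 4 of 9 regions higher and 2 lower, the same as adjusted over the list alone. The list passed at 0.83 with consecutive systematic numbers (adjusted p = 0.0031, and 0.37 with an estimated correlation) and lay at 0.15 without probes 3001 to 3300. GYP8-STE2 (1.56 ± 0.18), upstream of the alpha-factor receptor gene, and SNL1-BAR1 (1.51 ± 0.12), upstream of the protease that degrades alpha-factor, were higher, and STE3-LST4, upstream of the a-factor receptor gene, was lower (-0.94 ± 0.16). The STE2 call was lost without untagged array 1 (1.39), and that of STE3-LST4 with any 1 array left out (limma adjusted p between 0.055 and 0.097). The region upstream of SPT15, the gene of TBP, gave 0.68 ± 0.19 with a limma adjusted p = 0.063.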

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

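Regions without a value on some array were left out of the main comparison of the strains. Limma tested 405 of them, with values on at least 2 HA-TBP arrays and 1 untagged array. Of these, 54 (13.3%) were called higher in HA-TBP than in the untagged strain and 4 lower, at an adjusted p under 0.05. The calls lie in data outside the main comparison. Of the 54 regions, 52 had a dim spot, as did 89.4% of all 405. For 30 of the 54 no residual degree of freedom was left, so their p rests on the spread borrowed from other regions. Their difference is 1 HA-TBP array minus 1 untagged array of the same channel order, as the other HA-TBP array fits the dye term. A call here need not mean that every HA-TBP array lay above the control. At probe 864, which kept both untagged arrays, untagged array 2 lay above both measured HA-TBP arrays once centred. No explanation of these calls was tested.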

How the results depend on the processing

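The alternatives on dim spots, probe numbers, systematic numbers and polymerase III neighbours, and the estimated correlation combined with these or with other settings, were chosen after seeing the data. No paired analysis was possible because the replicate numbers follow accession order and pair nothing. The TATA box comparison was not run, because no genome sequence was used here. Without untagged array 2 and without HA-TBP array 3 the fit rests on the same contrast, so both gave 619 higher and 73 lower regions. That contrast is the mean of HA-TBP arrays 1 and 2 minus untagged array 1. Without untagged array 1 the difference is HA-TBP array 3 minus untagged array 2. HA-TBP arrays 1 and 2 then serve only the dye term and the spread. Where 1 untagged array is left, it is assumed to vary like the rest. Where the cause of a change is not given, the cause was not tested.

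Against 918 higher and 468 lower regions, the values as deposited gave 0 and 0 and quantile normalization 0 and 0; uncentred arrays differ in median, which widens the spread. Centring on the mode gave 122 lower, all shared with the 468. The looser filter on missing values gave 216 lower, the robust trend 888, no dim spots 816 and adjusted p thresholds of 0.01 and 0.10 gave 3 and 1051; at 0.01, 481 were higher. Of all calls, 66.2% were higher, against 79.0% with the looser filter, 53.2% with the robust trend and 54.4% without dim spots. Leaving out 1 array gave 312 to 700 higher and 22 to 74 lower, lowest in both without untagged array 1. Without the probe block 905 were higher and 465 lower. Called above 0 in HA-TBP were 1610 regions, but 0 as deposited, 986 with quantile normalization, 971 at 0.01 and 871 to 1522 with 1 array left out. Called above 0 in the untagged strain were 520 with scaled arrays, 354 with quantile normalization, 4 at 0.10, 38 without dim spots and 0 to 38 with 1 array left out.

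Without dim spots the lowest r within HA-TBP was 0.82 and the highest between strains 0.23; Spearman's rho was 0.46 within the untagged strain and at most 0.23 between strains. With an estimated correlation the shifts of polymerase III genes (1.84), histones (1.06), ribosomal proteins (0.88), glycolysis (0.82) and ribosome biogenesis (0.39) and the divergent to tandem gap (0.17) no longer passed. That setting tests on 2 residual degrees of freedom, so these losses do not by themselves argue against the shifts. Histones did not pass in HA-TBP alone (0.90). Ribosome biogenesis did not pass with scaled arrays (0.20) or tandem regions only (0.27), and ranged from 0.31 to 0.45 with 1 array left out. Lists that came to pass were glucose-repressed genes (-0.28 with consecutive numbers, -0.40 without polymerase III neighbours), mating (0.83 with consecutive numbers) and meiosis (-0.42 scaled, -0.37 with consecutive numbers, -0.44 without polymerase III neighbours, -0.48 without HA-TBP array 1 and -0.59 without untagged array 1); without each other array meiosis did not pass, and with 1 array left out it ranged from -0.59 to -0.26. As deposited, YDJ1-MTQ1 (-0.25) and UBI4-ENT4 (-0.33) reversed sign. Of the 38 named regions that passed, 38 lost their call with quantile normalization, 36 as deposited (besides the reversed ones), 23 without untagged array 1, 18 at 0.01 and at most 11 under each other setting.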

Other observations

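All tests in this part were chosen after the result was seen. Of 14 gene families picked by symbol, 7 lay above and 2 below other regions with camera at the preset correlation, and 0 passed with an estimated one. The estimated setting tests on 2 residual degrees of freedom, where few families could pass. Regions upstream of proteasome subunits lay 0.68 above other regions on the log2 scale, with 20 of 30 higher and 1 lower (adjusted p = 4.7e-08 over the families, and 0.27 with an estimated correlation). Translation factors lay 0.61 above, with 16 of 32 higher and 0 lower (adjusted p = 2.7e-06, and 0.27 with an estimated correlation). Seripauperins, a subtelomeric cell wall family, lay at -0.40, with 2 of 27 higher and 8 lower (adjusted p = 0.0020), and hexose transporters at -0.38, with 0 of 19 higher and 6 lower (adjusted p = 0.030); with an estimated correlation both gave an adjusted p = 0.27. These 4 shifts kept their sign when arrays were scaled or quantile normalized. Of the family regions, 1 of the proteasome, 2 of the translation factors, 3 of the seripauperins and 0 of the hexose transporters adjoined a polymerase III gene. Among other families that lay above, so did 2 of 18 nuclear pore and 1 of 15 vacuolar ATPase regions. The families were not tested without these regions. Some regions also lie upstream of a ribosomal protein gene, such as RPL11A-PRE2 of the proteasome. Probes of near-identical family members can share signal.

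Among regions between protein-coding genes with no dim spot, those after SOP4-RPS14B were both probes of NTG1-SYN8 (3.17 ± 0.20 and 3.14 ± 0.14), the convergent OLE1-ERV14 (2.84 ± 0.21), which has a polymerase III gene 1 gene away, and GTS1-ATG1 (2.67 ± 0.22). The 894 regions with neighbours not known here held 175 higher and 50 lower calls, and 31.5% of them had a dim spot. The log2 difference fell slightly with probe number (Spearman rho = -0.12 across regions), and with a loess trend over probe number removed 878 regions were higher and 371 lower.

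There were 31 regions lower in HA-TBP by over 2-fold, of which 4 stayed called without untagged array 1 and 14 to 21 without each other array. Of these, 11 lay in probes 3001 to 3300, which hold 3.78% of regions (scan permutation p = 0.0001, the smallest that 10000 permutations give), and there untagged array 1 was over 1 above its median in 12.8% of regions against 1.67% elsewhere (odds ratio 6.95 without the called regions, Fisher's exact p = 6.7e-11). Untagged array 2 (6.38 against 3.46%, odds ratio 1.89 without the called regions, Fisher's exact p = 0.038) and HA-TBP array 2 (19.1 against 13.7%, odds ratio 1.58 likewise, Fisher's exact p = 0.010) were also raised there. HA-TBP arrays 1 (13.2 against 13.7%) and 3 (14.0 against 13.7%) were not detectably raised. These p-values are not adjusted over the arrays, and a rise on an HA-TBP array would not make regions lower in HA-TBP. A local fault, strongest on untagged array 1, may account for those 11, while the other 20 lay outside the block. Dim spots were commoner among the 31 than among all regions (17 of 31, odds ratio 4.97, Fisher's exact p = 1.6e-05) and may account for part of them, but 14 had none. With arrays centred on their mode 22 of the 31 were still called lower, but that centring moves every region by the same amount, so whether centring contributes stays open, as does whether the background of the untagged strain differs there.

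Antisense and miscellaneous RNA genes were left out when neighbours were assigned. Convergent regions hold no promoter of their neighbouring genes, yet 17 of 1211 were higher, such as YPR1-XRS2 (1.66 ± 0.17). Of these, 10 had no dim spot, which argues against dim spots for them; the 7 with a dim spot are undecided (odds ratio 1.94, Fisher's exact p = 0.18). A gene of the systematic numbering that the assembly lacks is argued against for the 14 whose neighbours have consecutive systematic numbers. It is undecided for the other 3 (Fisher's exact p = 0.094). Genes with an RNA tag or a letter suffix leave no gap in the numbers, so for them this check cannot tell. Signal from a polymerase III gene beyond either neighbour may account for 4, among them OLE1-ERV14 and KRE6-YPR159C-A (2.43 ± 0.23) (odds ratio 3.64, Fisher's exact p = 0.041), but 13 had no such gene there. Other start sites, annotated or not, are an untested hypothesis for the rest.

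At 138 tRNA genes the 5' flank was higher for 75 (exact sign test p = 0.35) and the mean 5' minus 3' difference was -0.15 (permutation p = 0.14), but 31 genes had only the 3' flank called higher and 8 only the 5' flank (exact McNemar test p = 2.9e-04). Of these, 28 and 2 were on the Watson strand. Split by strand, the 5' flank was higher for 23 of 72 genes on the Watson strand (exact sign test p = 0.0029) and for 52 of 66 on the Crick strand (p = 2.8e-06), so that the right-hand flank was higher for 101 of the genes, with a mean right minus left difference of 0.56 over all 138, and TBP nearer the 5' flank, where the initiation factor TFIIIB binds, does not account for this. A gene of the systematic numbering, missing from the assembly on the left, is argued against. Of 113 tRNA genes between consecutive systematic numbers, 83 had the higher right-hand flank too (exact sign test p = 6.3e-07). A missing gene with an RNA tag or a letter suffix would leave no gap in the numbers, so this check cannot tell for such genes. Probes that reach the gene naming them but not always the next gene stay open, and for such regions the right-hand promoter could lie outside the probe.

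The high signal upstream of STE2 and BAR1 prompted the hypothesis that the cells were of mating type a. It was first tried on 7 genes, 5 a-specific and 2 alpha-specific, which gave a difference of 1.90 (exact permutation p = 0.048). That set was incomplete. With all 11 genes of a fuller list, 7 a-specific (mean 1.07) and 4 alpha-specific (mean 0.06), the difference was 1.01 (two-sided exact permutation p = 0.18), because the a-specific ASG7 lay at -1.06 while the alpha-specific MF(ALPHA)2 was among the higher regions. The region upstream of STE6 also adjoins a polymerase III gene. The hypothesis is not borne out by the fuller set, and the first p came from a selected list.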
